A study of Mus musculus with 4 samples.

How the data were processed

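Poly-A selected RNA from whole mouse hearts was sequenced in 4 libraries, 1 for each combination of 2 stages and 2 genotypes. The genotypes were a double knockout (dKO) of both miR-1 genes, miR-1-1 and its paralog miR-1-2, and a littermate control (dHET), in mice of the strain labelled Sv129. Per the labels, the postnatal day 2.5 (P2.5) libraries were read from a single end and the embryonic day 15.5 (E15.5) libraries from both ends, each with reads of 100 bases. RNA was extracted with TRIzol, per the labels' protocols.

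The authors' deposited values were FPKM, fragments per kilobase of transcript and 1000000 fragments, in 1 table per stage with 22552 gene rows each. TopHat, Bowtie, Cufflinks and the mouse genome build mm9 are named in the submitters' processing notes, which give no versions. The columns of the deposited tables also held the authors' log2 fold change, p-value, q-value and a status flag per gene. In the P2.5 table the deposited fold change is dKO over control. In the E15.5 table it is control over dKO, and its sign was turned for the values given here. The E15.5 table names its control column WT, whereas the sample labels name the control dHET; the column was taken as the dHET library because it is the only control sample at that stage. The settings of the authors' scaling and of their treatment of reads with several matches are not given in the sources used here.

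In each table, 86 rows were displaced by commas inside gene names and were realigned on their position column. Another 25 gene names had been turned into dates and were used as they stand. Rows flagged as OK or as having too few fragments for the authors' test were used. Other rows were left out of the calculations, among them Myh6 at P2.5 and Myh7 at E15.5, which were listed at 0 in the dKO library under a flag for too much data. An exact 0 in these tables can be a failed estimate.

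For each gene the change was computed as log2((FPKM dKO + 1)/(FPKM dHET + 1)), within a stage only, and all fold changes are on this scale, which understates changes of low genes. Genes with an FPKM of at least 5 in either library were counted as higher or lower at a fold of at least 1.5. With 1 library per group there is no replicate check and no test within a stage was possible. A test across the 2 within-stage changes, with 1 degree of freedom, was not made, and no p-value or standard deviation between samples was computed; standard errors of group means and the bootstrap interval are over genes. Where the authors' own significance calls are given, they compare 2 libraries, not genotypes.

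For 30 gene lists fixed before the data were examined, the median change of members with an FPKM of at least 1 was set among 10000 random lists of the same size matched on mean expression in 20 bins. A list was called apart when its median fell outside the central 95% of the random lists. This describes these libraries and is not a test of the genotype. With members drawn independently, 1.5 of 30 lists per stage would fall outside. Members of a real list can change together and some lists share members, so more can fall outside without any effect of the genotype. Apart on the higher and lower sides were 7 and 6 lists at P2.5, and 6 and 5 at E15.5. The named genes followed a rule that was also fixed before the data were examined: the 12 with the largest positive and the 12 with the largest negative change per stage, up to 4 members of each list with the largest absolute change, the 10 with the largest change in the same direction at both stages, and Esrrb, Mib1, Hand2, Hdac4, Irx5, Myocd, Nppa, Nppb, Myh6, Myh7 and Xist in every case. The first group left out names of predicted genes and of microRNA, snoRNA, snRNA and rRNA genes. That rule did not cover the short RNA gene Rmrp. Genes changed at both stages were ranked by the smaller of their 2 absolute changes. Genes named outside this rule are marked as such.

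Target sites of miR-1 were searched in the longest annotated 3' UTR per gene, from GENCODE release M1 transcripts on the build NCBIM37, which is the assembly of mm9. The words were ACATTCC and CATTCCA (7 bases) and ACATTCCA (8 bases), with GGACCAA of miR-133 as a comparison. Each word's carriers were set among 10000 random lists matched on expression and 3' UTR length. All 16384 words of 7 bases were also ranked by the difference in mean change between genes with and without them, after a linear fit on 3' UTR length and GC content. A ranking by that difference over its standard error was added after seeing the data.

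A scaling total was recovered from the low FPKM values, since a gene's value for 1 fragment depends on its length and on the library's scaling total. A fragment is 1 read in the P2.5 libraries and a pair of reads in the E15.5 libraries. This gave scaling totals of 44600000 and 49900000 for the P2.5 dHET and dKO libraries. They could differ from the number of mapped reads, since the authors' scaling is not described. The E15.5 totals were 86500000 and 104000000 for dHET and dKO. Between 80.1% and 82.1% of low values were then whole fragments within 0.1, against 20% by chance. An FPKM of 5 over 1 kilobase corresponds to 223, 250, 432 and 520 fragments in that order, with counting errors of 6.70%, 6.33%, 4.81% and 4.39%. These cover counting error only and no difference between animals.

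The calculations were tested on simulated data. For P2.5, 7920 genes were simulated with 200 changed by 2-fold, of which 100% were recovered with 0 others called, and 10 of 200 random lists fell outside the central 95%. For E15.5, with 8209 genes, 100% of 200 were recovered with 0 others called and 11 of 200 random lists fell outside. The simulated noise was narrower than the real changes, whose standard deviation over genes was 0.316 at P2.5 and 0.177 at E15.5. Only well-expressed genes were changed. The recovery thus checks the calculations and says nothing about false calls in the real data. A word given a simulated effect ranked 25 at P2.5 and 2 at E15.5 by plain difference, and 1 at both by standardised difference.

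Copies of transcripts elsewhere in NCBIM37 were found with blastn 2.17.0 at an identity of at least 95% over at least 100 bases. The alternatives tried were pseudocounts of 0.1 and 5, centring on the median change, rescaling to a sum of 1000000 per library, an FPKM filter of 10 or none, a fold of 2, all status flags, 10 expression bins and the shortest 3' UTR. Added after seeing the data were an adjustment for transcript GC content and length that keeps the mean change, a count without sex chromosome genes, the use of a gene's own row before a joint row of 2 names and the standardised word ranking. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, pysam 0.24.0 and matplotlib 3.10.9 were used.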

Results

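Whole-heart transcriptomes of mice lacking both miR-1 genes were compared with those of littermate controls at P2.5 and at E15.5. The microRNA miR-1 is abundant in heart muscle and lowers the messenger RNAs whose 3' UTR pairs with its seed. Each stage had 1 dKO and 1 dHET library, so no value below has a replicate error, and every difference is between 2 libraries. The scaling totals recovered from the tables, which need not equal the mapped reads, were 44600000 (dHET) and 49900000 (dKO) at P2.5, and 86500000 (dHET) and 104000000 (dKO) at E15.5. Between 11534 and 11627 genes had an FPKM of at least 1. Stages are compared through their within-stage changes only, since they were read and normalised separately.

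The targeted genes could not serve as a check of the labels. Mir1a-1 (chromosome 2, 180123753 to 180123829, mm9) and Mir1a-2 (chromosome 18) were listed at 0 in all 4 libraries, as was Mir133a-1, the chromosome 18 neighbour from the same cluster. Mir133a-2 was listed at 0 in 3 libraries and at 1.73 FPKM in the P2.5 dKO library. Poly-A RNA need not contain such short hairpin genes, so a value of 0 in it checks nothing. Mib1 (chromosome 18, 10725546 to 10818702), whose gene contains the chromosome 18 cluster, had 9.60 FPKM in dHET and 9.75 in dKO at P2.5, and 14.3 and 12.3 at E15.5.

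The first comparison asked which transcripts differ in the newborn heart without miR-1. At P2.5 some atrial, fetal heart muscle and smooth muscle genes were higher in the dKO library, at least 1.5-fold in 4 of 14, 6 of 21 and 5 of 19 members of their lists; the atrial and fetal calls depended on the processing. Nppa (chromosome 4, 147374831 to 147376188), which encodes atrial natriuretic peptide, had 182 FPKM in dHET and 1021 in dKO, a log2 change of 2.48. The atrial light chains Myl7 and Myl4 changed by 1.92 and 1.16, from 41.7 to 161 FPKM and from 29.0 to 66.0. Smooth muscle actin Acta2 changed from 658 to 1692 FPKM, and calponin Cnn1 from 15.9 to 53.5. In the same pair of libraries the X-inactivation transcript Xist was at 0.101 FPKM in dHET and 50.7 in dKO, and the Y-linked Ddx3y and Eif2s3y were at 11.7 and 36.1 FPKM in dHET and at 0 and 0.0113 in dKO. The P2.5 dHET library thus had a male pattern of these genes and the dKO library a female one, so genotype and sex differ together in every P2.5 comparison.

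Of 8197 genes counted at P2.5, 294 were at least 1.5-fold higher in dKO and 94 lower; 43 were at least 2-fold higher and 21 lower. This split depends on the scaling. Centring on the median change gave 184 higher and 157 lower, and rescaling each library to a sum of 1000000 gave 159 higher and 296 lower, since it moved the median change of all counted genes by -0.15, from 0.083 to -0.070. The changes of genes and lists are therefore read relative to the other genes of the library. In the authors' deposited table, 55 genes are called significant between these 2 libraries, 37 higher and 18 lower in dKO.

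Fetal heart genes, a list of genes active before birth, had a median change of 0.44 at P2.5, above all 10000 random lists. Of its 21 measured members, 6 were at least 1.5-fold higher and 1 was lower, Xirp2, named after its values were seen (1.08 to 0.282 FPKM). Of the list, 5 members lay below 0, among them Myh7, the fetal ventricular myosin (595 to 464 FPKM, -0.36). Smooth muscle genes had a median of 0.27 (99.3rd percentile), with 5 of 19 members higher, among them Tpm2 (37.8 to 87.8 FPKM) and Myl9 (464 to 792). Atrial genes had a median of 0.26 (98.0th percentile), with 4 of 14 higher and 1 lower (Kcnj3, outside the naming rule, at -0.92); Sln, which encodes an inhibitor of the calcium pump, went from 1.08 to 5.01 FPKM. The fetal list was no longer apart after adjustment for transcript GC content and length (92.3rd percentile), and the atrial list was not apart under 4 of the settings tried. These lists share Nppa and Myl4. The smooth muscle and fetal lists share Acta2, Cnn1 and Myl9, and also Tagln and Actg2, both at -0.090 and outside the naming rule.

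Glycolysis genes were apart on the higher side at P2.5, with a median of 0.28 (99.7th percentile) and 5 of 24 members at least 1.5-fold higher. Slc16a3, a lactate transporter, went from 7.27 to 23.5 FPKM, and Pkm2 from 193 to 317. With a filter at FPKM 10 this list was no longer apart (97.05th percentile). Cell cycle genes had a median of 0.22 (99.7th percentile) and lay above 0 in 35 of 39 members, although 1 member, the kinesin Cenpe (0.64), passed 1.5-fold, and Ccnd2 was lower (-0.49). Genes of the stress and unfolded protein response had a median of 0.28 (99.3rd percentile), with Hsp90b1 at 0.63 and Dnajb9 at -0.32. Erythroid genes had a median of 0.60 over 4 measured members (99.9th percentile), with Tfrc at -0.30, and the haemoglobin members are near-identical copies that share reads. Hbb-b2, whose own row was not counted because a joint row with Hbb-b1 stood for it, went the other way (-1.34); with that row the median was 0.54 over 5 members (99.8th percentile). The stress and erythroid lists were no longer apart without a low-value filter, at percentiles of 79.7 and 49.0, and after adjustment for GC content and length, where their medians were 0.17 (92.4th percentile) and -0.11. The stress list was also not apart with a filter at FPKM 10 (95.97th percentile).

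Apart on the lower side at P2.5 were the macrophage, fibroblast, epicardial, immediate early and calcium handling lists, and the sex chromosome list (median -2.36). Macrophage and leukocyte markers had a median of -0.26 (0.02nd percentile), below 0 in 12 of 13 members, with S100a9 higher (0.86) and C1qc at 8.13 FPKM in dHET and 5.02 in dKO; a filter at FPKM 10 left 1 member, and the list was then not apart (5.38th percentile). Fibroblast markers had a median of -0.10 (0.66th percentile), with Mfap5 at -1.10, Lum at -0.72 and Dcn at -0.61. Of the 12 members 7 lay below 0 and 5 above, Col1a2 (0.36) among the latter. This list was no longer apart after adjustment for transcript GC content and length (-0.051, 2.99th percentile). Immediate early genes had a median of -0.12 (0.39th percentile), with Klf4 at -0.50, Fos at -0.38 and Ier2 at 0.40. Epicardial markers had a median of -0.15 (1.68th percentile) over 10 members, although the keratin Krt18 was higher (1.13). The epicardial call was lost with pseudocounts of 0.1 (2.77th percentile) and 5 (2.57th percentile), and turned to 0.71 over 2 members with a filter at FPKM 10. Calcium handling and ion channel genes had a median of -0.036 (0.64th percentile), with members on both sides. Phospholamban (Pln), the brake on the calcium pump, went from 1266 to 731 FPKM, while Casq2 and the gap junction gene Gja1 were higher (0.83 and 0.64).

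The other P2.5 lists lay within the random range. Cardiac sarcomere genes had a median of 0.21 with 4 of 28 higher (Myl7, Tnnc1, Tnnt2 and, outside the naming rule, Mybphl at 0.69) and 0 lower. Medians were 0.11 for fatty acid oxidation, 0.11 for oxidative phosphorylation, 0.087 for the tricarboxylic acid cycle and 0.015 for glycogen metabolism. Cardiac transcription factors had a median of 0.023 and collagen and matrix genes of 0.076. Estrogen-related receptors and coactivators had a median of 0.0091; Esrrb itself went from 3.18 to 6.55 FPKM, a change of 0.85. Described miR-1 targets had a median of 0.19 (97.3rd percentile), just within the random range. Of 35 members, 4 were at least 1.5-fold higher, among them Twf1, Gja1 and Myocd, and 1 was lower. Hand2 (0.42), Irx5 (0.42) and Hdac4 (-0.062) did not reach 1.5-fold. Myocd, a cofactor that turns on smooth muscle genes, changed by 0.62, and Nppb by 0.092.

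A few transcripts were nearly absent from the P2.5 dKO library. Rps18 went from 39.3 to 0.115 FPKM, Rps2 from 36.5 to 0.562, Rpl11 from 15.9 to 1.59, Hmgn2 from 18.3 to 1.47 and Rmrp from 12.4 to 0.437. Except for Rmrp these genes have near-identical copies elsewhere in the genome, so their values are uncertain. Ribosomal protein genes as a list had a median of 0.18, within the random range, but a mean of -0.25. Of 33 members, 6 were at least 1.5-fold lower and 3 higher, against 1.15% lower and 3.59% higher among all counted genes. Besides Rps18, Rps2 and Rpl11 the lower ones were Rpl30 (-1.07), Rps6 (-0.69) and, outside the naming rule, Rpl37 (-0.82), which also have copies elsewhere. Other genes among the 12 lowest were the RNA gene Snhg3 (-1.57), Rbfox1 (-1.32), Ddc (-1.17) and Hhatl (-1.14).

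**Figure D1:**
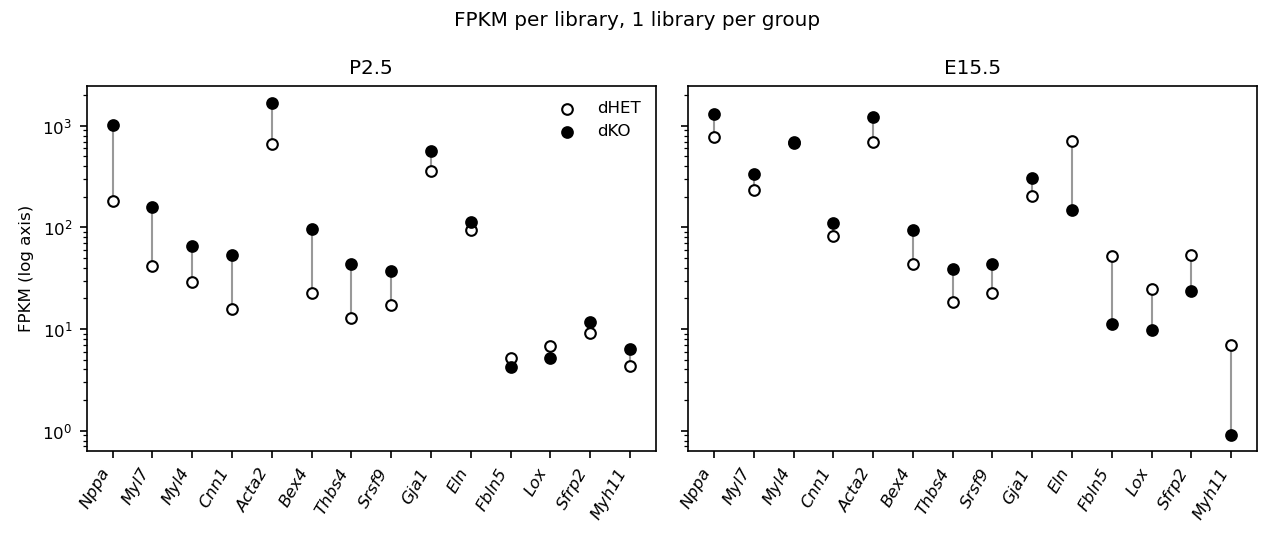
FPKM of 14 named genes in each library, on a log axis, at P2.5 (left) and E15.5 (right); open circles are dHET, filled circles dKO, 1 library each, with no error bars because there were no replicates. Nppa lay at 182 and 1021 FPKM at P2.5, and Eln at 710 and 147 FPKM at E15.5 (dHET and dKO).

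The second comparison put libraries labelled with the same genotypes side by side in the fetal heart. Among the 12 genes with the largest decrease in the E15.5 dKO library were Eln, Fbln5, Lox and Myh11, a grouping seen in the data and covered by no fixed list. Elastin (Eln, chromosome 5, 135179651 to 135223111) went from 710 FPKM in dHET to 147 in dKO, a log2 change of -2.26. Fibulin 5 (Fbln5) went from 52.1 to 11.1, the crosslinking enzyme Lox from 24.9 to 9.75 and smooth muscle myosin Myh11 from 6.95 to 0.915. Higher in dKO were Kcnmb1 (chromosome 11, 33863013 to 33873641), a subunit of the smooth muscle potassium channel, from 2.24 to 7.42 FPKM, and Nppa, from 775 to 1297. Both E15.5 libraries expressed Y-linked genes, with Ddx3y at 15.3 FPKM in dHET and 14.8 in dKO, and Xist was at 0.0550 and 0.113.

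Of 8308 genes counted at E15.5, 41 were at least 1.5-fold higher and 47 lower in dKO, with 8 and 15 at 2-fold. Changes within 1.2-fold made up 91.4% of genes, against 66.7% at P2.5. This does not compare the size of the genotype effect. The P2.5 libraries differed in sex, had smaller scaling totals and were read from a single end. The median standard error implied by the authors' values was 0.30 at P2.5 and 0.18 at E15.5. In the authors' deposited table, 135 genes are called significant between these 2 libraries, 42 higher and 93 lower in dKO. The control column of that table is headed WT, whereas the sample is labelled dHET.

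Atrial genes were apart on the higher side at E15.5, with a median of 0.18 (99.96th percentile), including Nppa (0.74), Sln (0.63) and Myl7 (0.51); 5 of 15 members were below 0, Dkk3 (-0.52) among them. Fetal heart genes had a median of 0.15 (99.93rd percentile), with 2 of 19 at least 1.5-fold higher (Nppa and Acta2) and 2 lower, Tnnt1 (-0.63) and, outside the naming rule, Actg2 (-1.39). Endothelial markers had a median of 0.13 (99.99th percentile) and 15 of 18 members above 0, such as Cldn5 (0.40), although none of them reached 1.5-fold. Oxidative phosphorylation genes had a median of 0.077 (99.86th percentile), with Ndufa1 at 0.48 and Ndufs3 at 0.46. Calcium handling and ion channel genes had a median of 0.062 (98.5th percentile), with Sln and Casq2 (0.59) higher and Kcne1 lower (-0.36); with a filter at FPKM 10 this list was no longer apart (96.5th percentile). The hypoxia response list lay at the edge, with a median of 0.071 (97.6th percentile), Ndrg1 at 0.43 and Bnip3 at -0.30, and was not apart under 8 of the settings tried.

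Cell cycle genes were lower at E15.5, with a median of -0.15, below all random lists, and 33 of 40 members below 0; Ube2c changed by -0.40, Cenpf by -0.33 and Ccnd1 by 0.30, and 0 members reached 1.5-fold. Collagen and matrix genes had a median of -0.10 (0.03rd percentile), with 3 of 34 members at least 1.5-fold lower (Eln, Lox and Bgn, the last at -0.60). Ribosomal protein genes had a median of -0.11 (0.05th percentile), with Rpl3 at -0.67 and Rps6 at -0.61; both have copies elsewhere in the genome, over 96.0% and 57.8% of their length, so these values are uncertain. Fibroblast markers had a median of -0.11 (1.02nd percentile), with Mfap5 at -0.69 and Tcf21 at 0.27; this list was no longer apart with a filter at FPKM 10. Cardiac sarcomere genes had a median of -0.086 (0.68th percentile), with Myom2 at -0.51, Tnni3 at -0.33 and Myl7 at 0.51; 10 of 28 members were above 0, and Myh6 changed by 0.070 (320 to 336 FPKM). Smooth muscle genes went both ways, with a median of -0.069 (5.94th percentile): Acta2 was higher (692 to 1215 FPKM) while Myh11, Rgs5 (-0.76), Actg2 and, outside the naming rule, Lmod1 (-1.24) were lower. This list was apart on the lower side after rescaling to a sum of 1000000 (1.81st percentile) and on the higher side with a filter at FPKM 10 (99.99th percentile).

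Other E15.5 lists lay within the random range. Glycolysis had a median of 0.030, although Pgam1 went from 26.5 to 56.0 FPKM. Medians were -0.047 for fatty acid oxidation, -0.028 for the tricarboxylic acid cycle, 0.018 for glycogen metabolism and -0.034 for cardiac transcription factors. Described miR-1 targets had a median of 0.034 (92.8th percentile), with Twf1 at 0.59 and Gja1 at 0.58. Esrrb went from 3.09 to 3.62 FPKM, Hand2 from 28.8 to 28.3 and Nppb from 54.1 to 64.7. Tpt1 (7.85 to 22.0 FPKM) and Pgam1 have near-identical copies elsewhere in the genome, so their changes are uncertain.

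**Figure D2:**
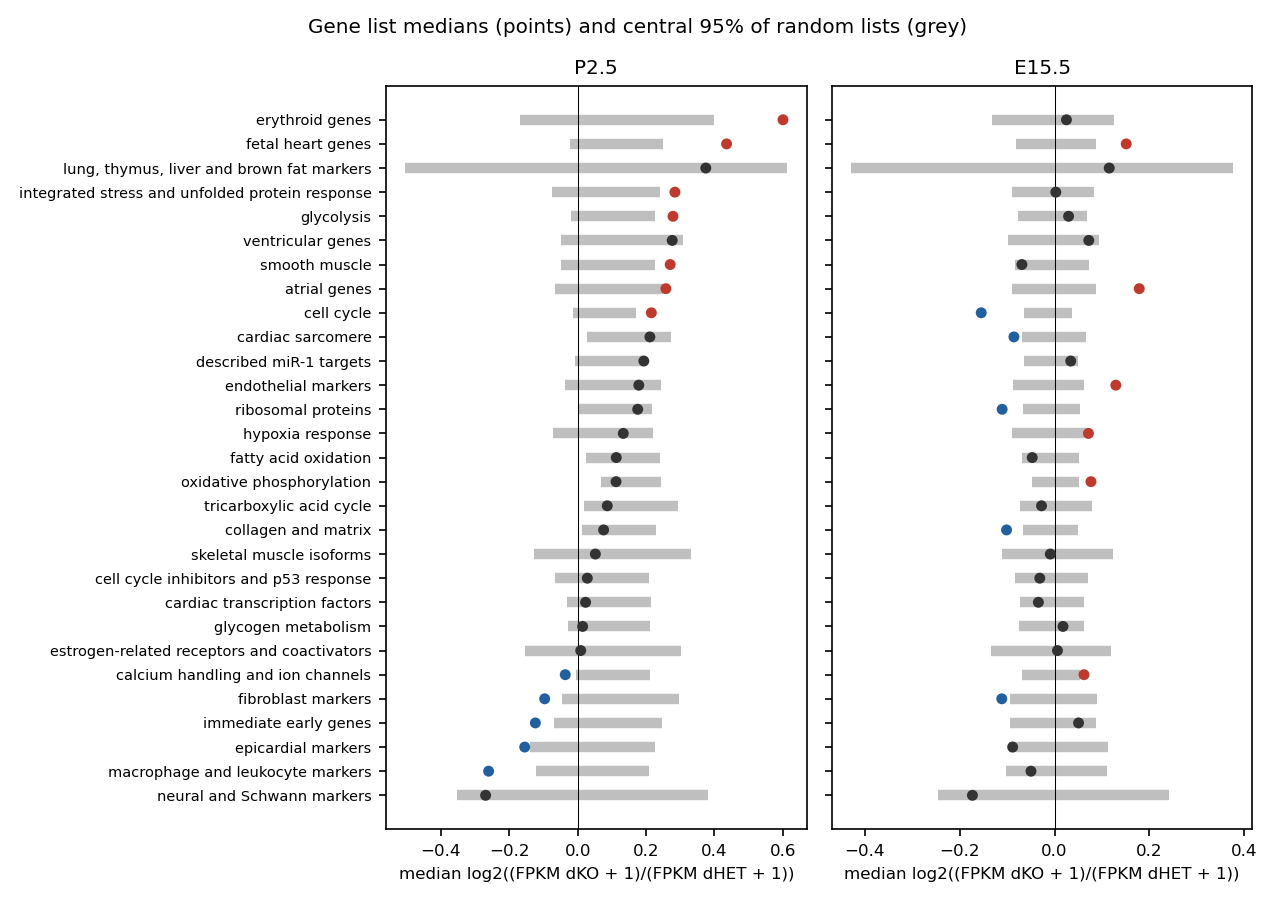
Median log2 change of each gene list (points) at P2.5 (left) and E15.5 (right), with the central 95% of random lists matched on expression as grey bars; red points lie above it, blue points below it, and the sex chromosome list is not drawn. Cell cycle genes lay at 0.22 at P2.5 and at -0.15 at E15.5.

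The changes at P2.5 and E15.5 were then set side by side, gene by gene, in pairs of libraries that have none in common. The control may differ in genotype between the pairs, since the E15.5 control column is headed WT. Over 7650 genes counted at both stages, Pearson's r was 0.403 (bootstrap 95% interval over genes 0.366 to 0.440) and Spearman's rho 0.402, and 63.0% of genes had the same sign. These are correlations across genes, which are not independent replicates. Changes also rose with transcript GC content at both stages (r of 0.356 at P2.5 and 0.180 at E15.5). The correlation between stages fell below the bootstrap interval after adjustment for GC content and length (0.357), without a low-value filter (0.321) and with all status flags (0.301). Higher at both stages by at least 1.5-fold were 26 genes, where independent lists would share 1.17, and lower at both were 8, where they would share 0.239. Ranked by the smaller of the 2 changes, the largest shared increases were those of Bex4 (2.06 at P2.5, 1.12 at E15.5), Thbs4 (1.70 and 1.05), Uhmk1 (1.00 and 1.04), Sdsl (1.19 and 0.99), Myl6 (1.23 and 0.98) and the splicing factor Srsf9 (1.08 and 0.92). Nppa, Acta2, Trappc4, Twf1, Sln and Casq2 were also higher at both. Nov (-0.95 and -1.05), Serpinb6b (-1.09 and -0.95), Ddc (-1.17 and -0.75) and Mfap5 (-1.10 and -0.69) were lower at both. Bex4 lies on the X chromosome and showed its increase also at E15.5, where both libraries expressed Y-linked genes.

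**Figure D3:**
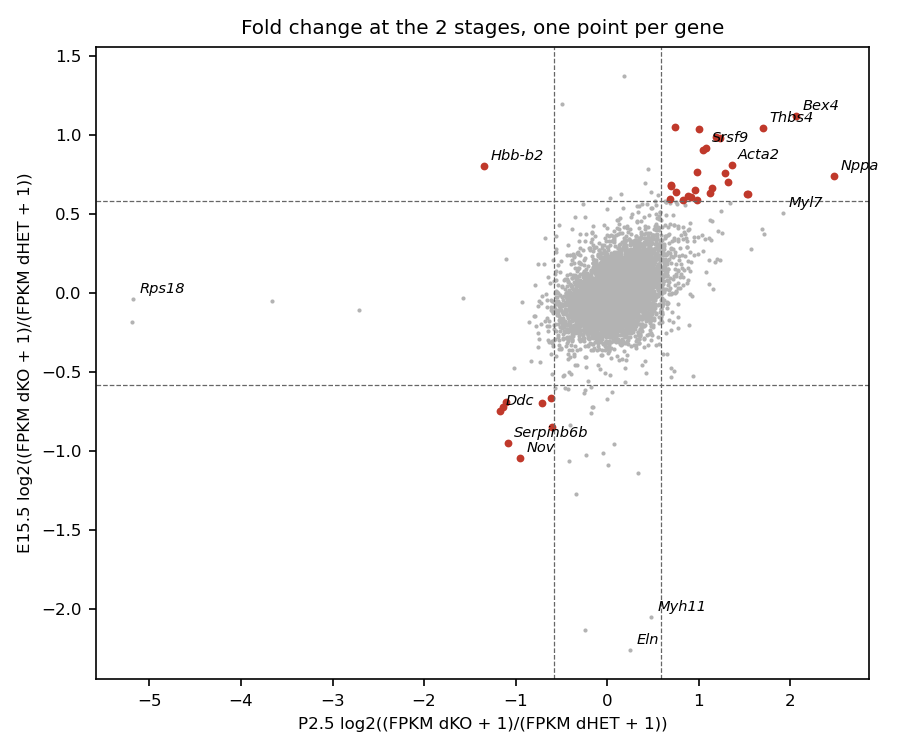
Log2 change at P2.5 (horizontal axis) against E15.5 (vertical axis), 1 point per gene counted at both stages, with dashed lines at 1.5-fold and red points for genes past them at both stages. Pearson's r over the 7650 genes was 0.403, and Hbb-b2 was the 1 gene past the lines in opposite directions.

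The last comparison asked whether genes that carry miR-1 sites differed from other genes. Genes with the miR-1 seed match ACATTCC in the 3' UTR had a median change of 0.070 at P2.5 (1249 genes) and 0.023 at E15.5 (1266 genes), above all random lists matched on expression and 3' UTR length at both stages. Without that matching the medians of genes with and without the word were 0.070 and 0.066 at P2.5, and 0.023 and -0.012 at E15.5. Carriers of the 8-base match ACATTCCA had medians of 0.096 and 0.049. Genes with the miR-133 word GGACCAA also lay at the 99.99th percentile at both stages, but this was lost at P2.5 after adjustment for transcript GC content and length (82.9th percentile) and at E15.5 without a low-value filter (96.8th percentile). Carriers of ACATTCC stayed above all random lists under these settings, whereas those of the other miR-1 word, CATTCCA, were no longer outside the range at E15.5 without the filter, with a median of 0.

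Ranking all 16384 words of 7 bases separated the 2 microRNAs. After the fit on 3' UTR length and GC content, ACATTCC ranked 7 at P2.5 and 4 at E15.5 by difference in mean change (0.081 and 0.057), CATTCCA ranked 74 and 38, and GGACCAA 1804 and 1468. Ranked by the difference over its standard error, which was added after seeing the data, ACATTCC was 1 and CATTCCA 2 at both stages, and GGACCAA was 1139 and 952. Of the 26 genes higher at both stages, 17 carried ACATTCC or CATTCCA, against 4 in the median of random sets matched on 3' UTR length and 7 at the upper bound of their central 95%; of all 7519 genes counted at both stages with an annotated 3' UTR, 1354 carried one. Among the 8 genes lower at both stages, 1 carried a site, the same as the median of 1 in matched random sets (central 95% from 0 to 3).

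The sites below lie in annotated 3' UTRs on mm9, in genes higher at both stages except Kcnmb1 and Gja1, which did not meet that rule. In Srsf9 an ACATTCCA site lies on chromosome 5 at 115782794 to 115782801, 66 bases past the stop codon, in the sequence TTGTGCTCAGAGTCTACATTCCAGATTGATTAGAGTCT. The 3' UTR of Twf1, a described miR-1 target that encodes an actin-binding protein, has ACATTCCA on chromosome 15 at 94408601 to 94408608 and CATTCCA at 94410174 to 94410180. Bex4 has ACATTCC on the X chromosome at 132674897 to 132674903, in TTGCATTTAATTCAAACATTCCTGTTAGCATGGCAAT. Kcnmb1 has ACATTCCA on chromosome 11 at 33873178 to 33873185. In Gja1, which encodes connexin 43, ACATTCCA occurs on chromosome 10 at 56108978 to 56108985 and again at 56110102 to 56110109; its FPKM was 363 in dHET and 567 in dKO at P2.5, and 203 and 304 at E15.5.

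**Figure D4:**
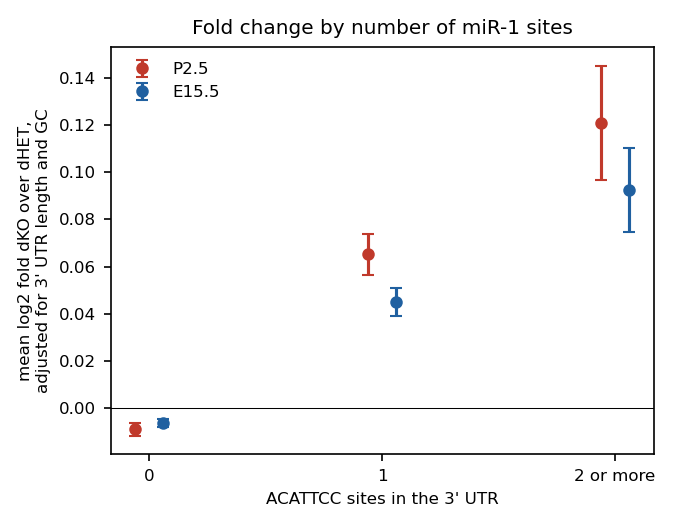
Mean log2 change adjusted for 3' UTR length and GC content, by the number of ACATTCC sites in the 3' UTR, at P2.5 (red) and E15.5 (blue); bars are standard errors over genes, which are not replicates. The mean was -0.0089 with 0 sites, 0.065 with 1 and 0.12 with 2 or more at P2.5, and -0.0064, 0.045 and 0.092 at E15.5.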

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

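Tests of an effect present at both stages, of vessel tissue at E15.5 and of genes not on the X chromosome, the form of the GC and length adjustment and the form of the test of genomic copies were chosen only after results were seen. Cell cycle genes went in opposite directions at the stages, apart from random lists on the higher side at P2.5 (0.22) and on the lower side at E15.5 (-0.15), a difference in medians of 0.37 that was not tested and depends on the scaling (0.22 after rescaling to a sum of 1000000). Calcium handling and ion channel genes lay on the lower side at P2.5 (-0.036) and on the higher side at E15.5 (0.062), a difference of -0.098, also untested (-0.26 after rescaling). Hbb-b2 (-1.34 at P2.5, 0.80 at E15.5) differed by -2.14 between the stages, untested, and shares reads with its near-identical neighbour.

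More genes were higher than lower in the P2.5 dKO library, at 3.13 higher genes per lower one. Among genes without a miR-1 site in the 3' UTR the value was 3. At this scaling, that argues against genes with a site as the whole cause. Of the 294 higher genes, 13 lay on the X chromosome, too few to make up the whole split. The value of 3.09 among genes not on the X chromosome could therefore hardly have differed, and it is no separate test. The planned test of X-linked genes did not decide, since they made up 4.42% of the higher genes, between the 2.84% among all counted genes and 2 times that, so a part of the split from them stays open. A trend with transcript GC content and length stays open too, since the fit gave 2.44 with the mean change kept and 0.972 as first run, without it, and the level chosen sets the value; centring alone gave 184 higher and 157 lower. Scaling between the libraries also stays open, since rescaling to a sum of 1000000 gave 159 higher and 296 lower, and so do effects of sex on other chromosomes, untested and confounded with genotype at P2.5.

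Rps18, Rps2, Rpl11, Hmgn2 and Rmrp were nearly absent from the P2.5 dKO library. A loss caused by the knockout at both stages is argued against for Rps18 (-0.041) and Rpl11 (-0.11), with a median of -0.075 at E15.5, and stays open for Rps2, Hmgn2 and Rmrp, of which 0 reached FPKM 5 there. Sharing of reads with genomic copies stays open for the 4 genes other than Rmrp: a median of 46.1% of their length had a copy elsewhere, close to the 45.1% of random sets with as many ribosomal protein genes, and 0 of 7 ribosomal protein genes with at least 90% of their length copied were lower by 1.5-fold. Rpl3, among these 7, was too low in both P2.5 libraries to be called lower. For Rmrp, taken from its deposited position because it had no annotated transcript, a share of 0% argues against it. A knockout effect limited to P2.5 was not tested.

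The elastic fibre genes Eln, Fbln5 and Lox and the smooth muscle gene Myh11 were among the 12 genes with the largest decrease in the E15.5 dKO library, while the fixed smooth muscle list lay within the random range (-0.069). At P2.5, 7 of these 12 genes had an FPKM of at least 5, with a median change of 0.014. This argues against an effect present at both stages for the 7 as a set, not for each gene. Gpc6 (-0.42), Lox (-0.34) and Fbln5 (-0.24) were lower at P2.5 too, while Eln (0.25), Sfrp2 (0.34), Myh11 (0.48) and Fbln2 (0.014) were not. The 12 were chosen for their decrease at E15.5, and sex differs with genotype at P2.5, which limits this comparison. For the 5 others, of which 0 reached an FPKM of 5 at P2.5, an effect at both stages stays open. Less outflow or great vessel tissue in the dKO sample could lower such genes together, but of 8 vessel wall markers outside the 12 genes, listed after the decrease had been seen, 5 were lower, 2 of them (Lmod1 and Actg2) under FPKM 5. Kcnmb1, Acta2 and Cnn1 were higher, and the fetal heart muscle also makes several of them, so tissue content and a stage-specific effect cannot be told apart with 1 sample per group.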

How the results depend on the processing

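No paired analysis was made. The groups share 1 replicate number only, and the 2 stages were not used as pairs for a test, which would have had 1 degree of freedom. No result therefore came from a test. The adjustment for transcript GC content and length, the count without sex chromosome genes, the use of a gene's own row before a joint row and the standardised word ranking were chosen after seeing the data. Of 537 list medians recomputed under the alternatives, 497 stayed on their side of the random range, 25 returned into it, 14 left it and 1 changed sides. At P2.5, smooth muscle, cell cycle, calcium handling and immediate early genes stayed apart under every setting tried for lists. At E15.5 this held for sarcomere, fetal, atrial, endothelial, oxidative phosphorylation, cell cycle, collagen and ribosomal genes. ACATTCC ranked 1 by standardised difference under all settings tried for sites. For changes below, the cause was not tested unless a filter left fewer genes. Depth limits low genes most, since 3 reads over 1 kilobase equal an FPKM of 0.0673 in the library with the smallest scaling total.

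With a pseudocount of 5, 140 genes were higher and 38 lower at P2.5, 18 and 21 at E15.5, and 9 higher and 1 lower at both stages. The medians were 0.16 for described miR-1 targets at P2.5, now apart, and -0.071 (epicardial, P2.5) and 0.049 (hypoxia, E15.5), no longer apart; CATTCCA ranked 25 at E15.5. With a pseudocount of 0.1, epicardial (-0.17) and atrial (0.26) genes at P2.5 and hypoxia genes at E15.5 (0.076) were no longer apart, smooth muscle at E15.5 (-0.10) was, and ACATTCC ranked 14 at P2.5. Centring gave 184 higher and 157 lower at P2.5. Rescaling to a sum of 1000000 gave 159 higher and 296 lower at P2.5 and 13 lower at both stages. It ended the calls of atrial genes at P2.5 (0.10) and hypoxia genes at E15.5 (0.078), set smooth muscle apart at E15.5 (-0.094) and put ACATTCC at 14 at P2.5.

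A filter at FPKM 10, which left fewer genes, gave 59 lower at P2.5, 26 higher and 24 lower at E15.5, and 16 higher and 2 lower at both stages. Epicardial markers at P2.5 changed sides, to 0.71 over 2 members. No longer apart at P2.5 were glycolysis (0.29), macrophage (-0.33), atrial (0.32) and stress response genes (0.31). At E15.5 these were calcium handling (0.052), fibroblast (-0.10) and hypoxia genes (0.071). Newly apart were cardiac transcription factors at P2.5 (-0.049) and, at E15.5, smooth muscle (0.21), described miR-1 targets (0.061), erythroid (0.15) and immediate early genes (0.15). ACATTCC ranked 26 at P2.5 and 17 at E15.5, and CATTCCA 83 at E15.5. Without a filter, 159 genes were lower at P2.5, 93 at E15.5 and 13 at both, and r was 0.321. Described miR-1 targets at P2.5 (0.19) and neural markers at E15.5 (-0.051) were then apart, and erythroid (0.0051) and stress response genes (0.091) at P2.5 and hypoxia genes at E15.5 (0.071) were not. Carriers of CATTCCA and GGACCAA at E15.5, both with a median of 0, were no longer outside the range; at P2.5 ACATTCC ranked 13 and CATTCCA 184.

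A fold of 2 gave 43 higher and 21 lower at P2.5, 8 and 15 at E15.5, and 3 higher and 0 lower at both. With all status flags r was 0.301, and hypoxia genes at E15.5 (0.071) were no longer apart; the same held for them with 10 expression bins (0.071), where described miR-1 targets at P2.5 (0.19) were apart. After the GC and length adjustment r was 0.357. At P2.5 fetal (0.18), fibroblast (-0.051), erythroid (-0.11), atrial (0.20) and stress response genes (0.17) and carriers of GGACCAA (0.074) were no longer outside the random range, nor were hypoxia genes at E15.5 (0.056). Smooth muscle (-0.081), cardiac transcription factors (-0.078) and described miR-1 targets (0.051) then were at E15.5. At P2.5 ACATTCC ranked 3, CATTCCA 43 and GGACCAA 2933. With the shortest 3' UTR, ACATTCC ranked 47 at P2.5 and 17 at E15.5, and CATTCCA 472 and 115. With a gene's own row used before a joint row, only the erythroid list changed members, with medians of 0.54 at P2.5 and 0.025 at E15.5 and the same calls. The standardised ranking put ACATTCC at 1 and CATTCCA at 2 at both stages, and GGACCAA at 1139 at P2.5 and 952 at E15.5. Of 2664 values of named genes, 93 moved by more than the authors' implied standard error, and 0 with a change of at least 1.5-fold turned sign. Myh6 at P2.5 and Myh7 at E15.5 had a value only with all status flags, where the dKO library was listed at 0.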

Other observations

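The tests of coding sequence and of site number below were set before their results were seen. Further list medians were as follows. Ventricular genes had a median of 0.28 at P2.5 (95.04th percentile) and 0.072 at E15.5 (93.4th percentile), with Irx3 at 0.73 and 0.34 and Cited1 at 0.85 and 0.37. Skeletal muscle isoforms had medians of 0.052 and -0.0090, although Casq1 was at 1.12 at P2.5 and Tnni2 at -1.06 at E15.5. Cell cycle inhibitors and p53 response genes had medians of 0.028 and -0.031, with Cdkn1a at -0.63 at P2.5. Hypoxia response genes had a median of 0.13 at P2.5. At E15.5 the medians were -0.050 for macrophage markers, -0.088 for epicardial markers, 0.051 for immediate early genes, 0.0026 for the stress response and 0.025 for erythroid genes. Endothelial markers had a median of 0.18 at P2.5. Neural and Schwann markers had 3 measured members, all below 0 at both stages (medians -0.27 and -0.17). Of the lung, thymus, liver and brown fat markers 1 was measured, Cidea (0.37 and 0.12). The sex chromosome list had medians of -2.36 at P2.5 and -0.089 at E15.5.

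A site for miR-1 may act by its place in the 3' UTR. In the coding sequence ACATTCC ranked 3602 at P2.5 and 3103 at E15.5 by standardised difference, which argues against its base composition alone. The mean change adjusted for 3' UTR length and GC content was larger with more sites at both stages. Unadjusted medians at P2.5 did not rise from 0 sites (0.066) to 1 (0.066), and were 0.11 with 2 or more. At E15.5 they were -0.012, 0.022 and 0.046. The smaller of the 2 differences in adjusted mean between genes with 2 or more ACATTCC sites and genes with 1 was 0.047, at E15.5. The standard errors over genes there were 0.018 and 0.0059. Genes are not replicates, and each difference rests on 2 libraries.

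Gapdh, chosen after its values were seen, was at 0.0546 and 0.211 FPKM at P2.5 and at 0.244 and 0.320 at E15.5 (dHET and dKO). It had 52 matching stretches elsewhere in the genome, over 88.6% of its transcript length.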
